A study of Homo sapiens with 15 samples.

How the data were processed

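RNA from MeT5A cells was hybridized as Cy3-labelled cDNA to NimbleGen whole human genome 12x135K arrays, 1 colour per array, per the labels' protocols. The 15 arrays fall into 5 groups of 3 (saline, dispersant, SWCNT, MWCNT and asbestos), as the sample labels give them. Particle stocks of 0.1 mg/mL were made with 150 µL/mL of the lung surfactant Survanta, for asbestos too, per the labels' protocols. The design text names dispersant as the control of the nanotubes and saline as the control of asbestos, and also sets every group against dispersant. The labels speak of further samples, which are not analysed here. The slide, scan and position of each array are not given in the sources used here, so no slide could enter a fit.

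The authors deposited 1 table of log2 expression values for the series, processed with RMA (robust multi-array averaging) per the submitters' processing notes, with no version given. The lowest value of every array lay just above the log2 of 50, which fits rows having been kept only when they reached 50 on all 15 arrays; this filter is inferred from the values, and genes switched off in any group would then be missing. Array medians ran from 8.2484 to 8.5548, so the arrays did not share 1 distribution, and the deposited values were used without further scaling. Arrays give no read depth, and the precision rests on the number of arrays and on the spread between them.

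Rows were named through the platform annotation (9163 rows) and, for rows without a symbol there, through RefSeq accessions in a human gene table of assembly GRCh38.p14 (361 rows). Of 21572 rows, 9524 (44.1%) had 1 symbol, 12048 had none and no row had several; unnamed rows were tested and counted but never named. For the 633 genes with more than 1 row, the row with the highest mean over all arrays stood for the gene. No coordinates of that assembly are given; it served for names, for chromosome membership and for which genes neighbour each other.

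Differences were tested with limma 3.58.1 in R 4.3.3. All 15 arrays entered 1 linear model with a mean per group, and moderated tests (eBayes, 10 residual and 3.99 prior degrees of freedom) were made for 6 differences between groups and for 2 differences of effects, SWCNT against dispersant or MWCNT against dispersant minus asbestos against saline. Rows with a Benjamini-Hochberg adjusted p under 0.05 were called changed, with no fold minimum, and adjusted p without another name is limma's. Errors given with log2 changes are limma's standard errors, and those with levels are SDs over 3 arrays. Gene lists were tested with limma's camera (preset inter-gene correlation 0.01, and again with the correlation estimated), adjusted over 21 lists in each comparison. The tests, the 21 lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 5 largest increases and decreases in each main comparison (3 in the others) among changed genes whose groups did not overlap and whose higher mean exceeded the median of all rows, up to 2 changed members of each of 10 primary lists in the main comparisons, and MMP2 everywhere; the 2 differences of effects had no overlap condition. Not every gene taken by the rule is printed. Other genes named, members of the same lists, were picked after their values were seen. Statmod 1.5.0 served limma's array weights.

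The fit was tested on simulated data. In a simulated SWCNT against dispersant comparison of 21572 rows, 50 rows each were changed by 0.5, 1, 2 or -1 on the log2 scale. Of these, 0%, 22%, 90% and 34% were recovered, and 9.88% of the calls were false, above the 0.05 that the adjusted p aims at. The other 21372 rows were unchanged, whereas 25.8% of rows were called in the real comparison. The adjusted p is stricter where few rows change, so these shares do not give the recovery in the real data. A simulated list shift in MWCNT against dispersant over 8748 genes was called, and no other list was.

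Correlations of effects were set beside 100 simulations of unchanged groups that shared the control arrays. Alternatives were to fit only the arrays compared, to quantile normalize again, to centre each array on its median, to leave out the 25% of rows with the lowest mean, to use trended and robust variances, array weights or a minimum of 1.5-fold, to average the rows of a gene, to block on the replicate number, to estimate the inter-gene correlation, and to leave out each replicate. Saline as the control of the nanotubes, dispersant as the control of asbestos and the split of the dispersant arrays between the nanotube effects were added after seeing the data. So were 4 further gene lists (antigen processing and presentation, cytosolic ribosomal proteins, mitochondrial respiratory chain and ATP synthase, and cilium assembly), adjusted over these 4. For chromosomes, the median change of a chromosome's genes was set against 10000 random gene sets matched on expression level and on gene density (protein-coding neighbours within 500 kb), over 138 chromosome comparisons. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for tables and figures.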

Results

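Gene expression was measured in MeT5A cells, an immortalized human cell line from the pleural mesothelium, the cell layer that lines the lung cavity. The cells were kept for 4 months and 16 passages with dispersed single-walled carbon nanotubes (SWCNT), dispersed multi-walled carbon nanotubes (MWCNT) or crocidolite asbestos at 0.02 µg/cm2. Saline and a lung surfactant used to disperse the particles (called dispersant here) served as the passage controls. Each of the 5 groups had 3 arrays, 15 in all, and each array gave log2 levels for 21572 rows, of which 9524 carried 1 gene symbol (8748 different genes). The labels describe triplicate wells of 1 cell line per treatment, and whether the wells stayed separate cultures through all passages is not settled there. Limma's p-values for rows therefore measure the spread between these arrays. Camera sets the genes of a list against the other genes. The chromosome p-values set a chromosome's genes against random sets of genes and hold no spread between arrays. The 3 arrays of each group also limit the precision.

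The arrays separated by group. Replicate arrays correlated across rows with r between 0.94 and 0.979, and rows are not independent replicates. The closest groups were SWCNT and asbestos (median r = 0.948 over 9 array pairs), and the farthest were dispersant and MWCNT (0.852). The 2 control groups correlated with a median r of 0.892. Principal component 1 held 31.3% of the variance and put the controls on the positive side and all particle groups on the negative side. Component 2 held 26.2% and put saline and MWCNT opposite dispersant, SWCNT and asbestos.

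**Figure D1:**
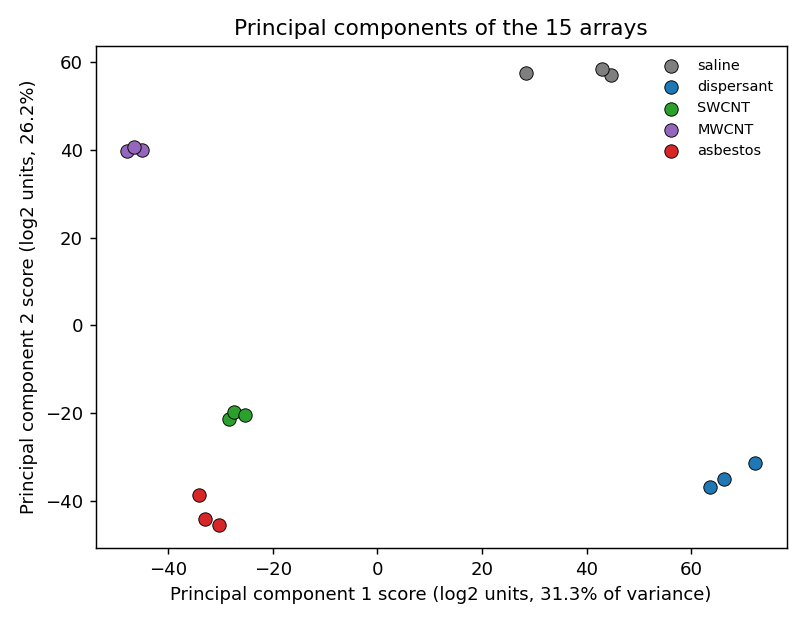
Scores of the 15 arrays on the first principal components of the deposited log2 values, 1 point per array, coloured by group. Both control groups lie at positive component 1 scores, while component 2 places saline and MWCNT above 0 and the other 3 groups below it.

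Cells kept with SWCNT were compared with dispersant controls to ask what the nanotubes changed beyond the dispersing agent. CXCR4, a chemokine receptor, was 31.6-fold higher (log2 change 4.98 ± 0.22 SE, adjusted p = 1.87e-08), with a mean log2 level of 12.08 ± 0.14 (SD, n = 3) against 7.1 ± 0.36. CEND1, a gene of cell cycle exit in neurons, was 18.1-fold higher, DCN (decorin, a matrix proteoglycan) 14-fold, and the interferon-induced genes MX2 and IFI6 13.2-fold and 9.11-fold. The deepest decreases were TCTN2, a protein of the ciliary base (10.2-fold lower, log2 change -3.35 ± 0.22, adjusted p = 1.25e-06), RASSF3 (9.0-fold), NAT1, an arylamine acetyltransferase (7.95-fold), STPG1 (6.3-fold) and CLTRN, a partner of amino acid transporters (5.81-fold). In each of these 10 genes all 3 arrays of one group lay beyond all 3 of the other, as the naming rule required.

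By gene list, 15 of the 17 measured interferon-stimulated genes rose in SWCNT and none fell (16 rose adjusted over the list alone). Their median log2 change was 1.65 above that of all genes (camera adjusted p = 3.15e-11; adjusted p = 0.00604 with an estimated correlation). Of 8 integrins, the receptors for matrix, 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0253; adjusted p = 0.103 with an estimated correlation), led by ITGA11 (log2 change 2.24 ± 0.36) while ITGA2 fell. Inflammatory cytokines and chemokines moved down as a list, with 5 of 15 lower and 1 higher (5 and 2 adjusted over the list alone; camera adjusted p = 0.0038; adjusted p = 0.103 with an estimated correlation). CSF3, the granulocyte colony-stimulating factor, was 4.64-fold lower and CXCL3 2.96-fold lower, whereas CCL2 rose by 1.19. Metallothioneins and iron handling genes shifted down with 2 of 11 lower, MT1F and MT1E (2 adjusted over the list alone; camera adjusted p = 0.0253; adjusted p = 0.259 with an estimated correlation), and near-identical metallothionein copies make these values uncertain.

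The other lists did not shift as a whole in SWCNT, though single members did. MMP2, a gelatinase that cuts basement membrane collagen, was 6.3-fold higher (log2 change 2.66 ± 0.23, adjusted p = 8.81e-06), and SERPINE2, a protease inhibitor, 6.83-fold higher. Of the 15 genes of matrix proteolysis 7 rose and 1 fell (7 and 1 adjusted over the list alone). Of 18 matrix genes 10 rose and 1 fell (10 and 1 adjusted over the list alone), with COL12A1 5.51-fold higher. Of 13 mesenchymal genes 5 rose and 1 fell (7 and 2 adjusted over the list alone), with TGFBI 3.71-fold and TWIST1 3.62-fold higher. KRT19, a simple-epithelium keratin, was 2.33-fold lower and MSLN (mesothelin) 2.24-fold higher. Of 11 mesothelial and keratin markers 3 were higher and 2 lower (4 and 2 adjusted over the list alone). AKR1C1 and AKR1C2, near-identical reductase genes whose separate values are uncertain, were 5.43-fold and 4.97-fold higher. Of 16 oxidative stress genes 7 were higher and 1 lower (7 and 1 adjusted over the list alone). The death receptor TNFRSF10B was 3.83-fold higher and the apoptosis gene BBC3 2.45-fold lower. Of 13 p53 targets 3 were higher and 1 lower (4 and 1 adjusted over the list alone). RRM2 and E2F1 were 2.3-fold and 1.92-fold higher, the only changes among 24 cell cycle genes (2 adjusted over the list alone). LATS2 and NF2, members of the Hippo growth control pathway, were 2.3-fold and 1.76-fold higher among 5 mesothelioma tumour suppressors (2 adjusted over the list alone). Of the 2 other NF2 rows, 1 was also called higher and 1 did not share the direction. The calls of MSLN (without dispersant replicate 1 or 3 or SWCNT replicate 2 or 3), E2F1 and NF2 (each without dispersant replicate 1 or 2 or SWCNT replicate 2 or 3) and CXCL3 (without SWCNT replicate 3) ended when that array was left out, with adjusted p up to 0.0977, 0.0891, 0.108 and 0.0603. Those of MSLN, E2F1 and NF2 also ended with centred arrays, a further quantile normalization or a fit of the compared arrays alone, and that of NF2 with its rows averaged. Over these settings adjusted p was 0.0686 to 0.132 for MSLN, 0.0715 to 0.0794 for E2F1 and 0.0541 to 0.106 for NF2.

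In all, 5564 of 21572 rows differed between SWCNT and dispersant, 4328 higher and 1236 lower (77.8% higher). Of these, 2921 differed by 2-fold or more. The median row was 0.228 log2 higher in SWCNT, so list changes are given relative to the median of all genes. With every array centred on its median the split was 2349 higher and 2301 lower (50.5% higher). With saline as the control, a comparison chosen after seeing the data, 3 of the 17 interferon-stimulated genes were higher and none lower (median change 0.109 above that of all genes, camera adjusted p = 0.412). Of 8 integrins 1 was higher and 4 lower than in saline, the opposite direction (median change -0.647 relative to all genes, camera adjusted p = 0.0747). The fall of metallothioneins and iron handling genes did not hold (camera adjusted p = 0.369), that of cytokines and chemokines did (8 of 15 lower and 1 higher, camera adjusted p = 0.000403; adjusted p = 0.0992 with an estimated correlation), and immediate early genes shifted down (camera adjusted p = 0.013; adjusted p = 0.197 with an estimated correlation). CXCR4 was 23.4-fold and MMP2 7.05-fold higher than in saline. The calls of IFI6, STPG1, MSLN, CXCL3, TNFRSF10B, BBC3, RRM2, E2F1, LATS2 and NF2 did not hold against saline (adjusted p from 0.0722 to 0.933).

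**Figure D2:**
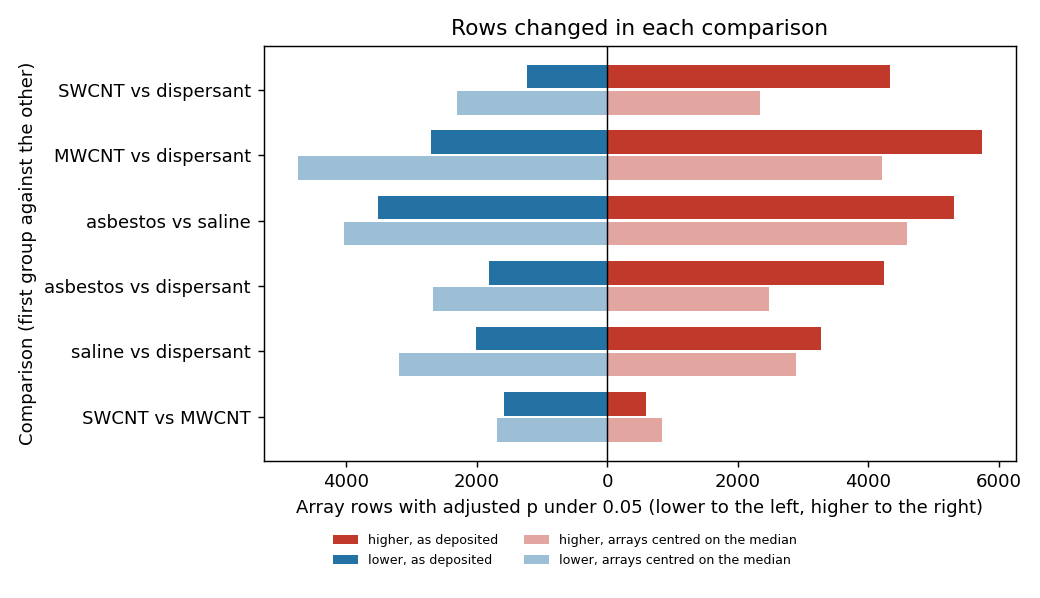
Numbers of array rows with adjusted p under 0.05 in each comparison, higher to the right and lower to the left, from the deposited values (dark bars) and with each array centred on its median (pale bars). Against dispersant, increases outnumbered decreases in the deposited values (77.8% higher in SWCNT, 68.1% in MWCNT), while the centred split lay near balance (50.5% and 47%).

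In MWCNT, CXCR4, CEND1 and DCN were again among the 5 largest increases, and TCTN2, CLTRN and STPG1 among the 5 largest decreases. CEND1 was 36.2-fold higher than in dispersant (log2 change 5.18 ± 0.20 SE, adjusted p = 1.69e-09), with a mean log2 level of 11.26 ± 0.088 (SD, n = 3) against 6.076 ± 0.20. It was followed by DCN (29.3-fold), CXCR4 (28.6-fold), the splicing factor gene SF3A2 (26.6-fold) and DNM2, the dynamin of endocytosis (22.4-fold). The deepest decreases were TCTN2 (10.7-fold lower), CLTRN (9.37-fold), ATP5MK, a small subunit of ATP synthase (9.27-fold), STPG1 (8.79-fold) and TMED4, a protein of the secretory pathway (8.76-fold). All 3 arrays of one group lay beyond all 3 of the other in each of these genes, as the naming rule required.

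Interferon-stimulated genes rose in MWCNT as well, 16 of 17 with none lower (16 adjusted over the list alone), at a median 1.86 above all genes (camera adjusted p = 7.33e-08; adjusted p = 0.0227 with an estimated correlation). MX2 was 14.6-fold and XAF1 7.81-fold higher. Of 8 integrins 6 rose (7 adjusted over the list alone), at a median 1.67 above all genes (camera adjusted p = 0.00107; adjusted p = 0.0287 with an estimated correlation). Among them ITGA3 rose the most (log2 change 3.70 ± 0.21). The matrix proteolysis list shifted up with 9 of 15 genes higher (9 adjusted over the list alone; camera adjusted p = 0.0153; adjusted p = 0.094 with an estimated correlation). It was led by SERPINE2 (7.39-fold) and MMP2 (6.09-fold, log2 change 2.61 ± 0.23, adjusted p = 1.65e-06). Inhibitors of these proteases were among the genes that rose, including TIMP1, TIMP2, TIMP3 and TIMP4. Collagens and other matrix genes also shifted up, 10 of 18 higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 0.0348; adjusted p = 0.094 with an estimated correlation). COL6A2 was 6.93-fold higher. Metallothioneins and iron handling genes shifted down, 6 of 11 lower (7 adjusted over the list alone; camera adjusted p = 0.000531; adjusted p = 0.1 with an estimated correlation). MT1E fell by 1.58 on the log2 scale.

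Among lists that did not shift as a whole, TGFBI and FN1 (fibronectin) were 3.2-fold and 2.59-fold higher, with 4 of 13 mesenchymal genes higher and 1 lower (4 and 1 adjusted over the list alone). KRT19 was 3.49-fold lower and BNC1 3.76-fold higher, with 3 of 11 mesothelial and keratin markers higher and 2 lower (3 and 2 adjusted over the list alone). IL1B and CXCL3 were 3.24-fold and 3.01-fold lower, with 4 of 15 cytokines and chemokines lower and 2 higher (4 and 2 adjusted over the list alone). TKT, a pentose phosphate enzyme, was 4.77-fold and AKR1C1 4.26-fold higher, with 7 of 16 oxidative stress genes higher and 2 lower (7 and 2 adjusted over the list alone). TNFRSF10B was 3.65-fold higher and BBC3 2.74-fold lower among 13 p53 targets, of which 4 rose and 1 fell (4 and 1 adjusted over the list alone). RRM2 and E2F1 were 3.97-fold and 3.64-fold higher, with 9 of 24 cell cycle genes higher and 1 lower (9 and 3 adjusted over the list alone). LATS2 and NF2 were 3.83-fold and 2.01-fold higher among 5 mesothelioma tumour suppressors (2 adjusted over the list alone). Of the 2 other NF2 rows, 1 was also called higher and 1 did not share the direction.

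In all, 8441 rows differed between MWCNT and dispersant, 5746 higher and 2695 lower (68.1% higher), and 4906 of them by 2-fold or more, with the median row 0.165 higher. Centring the arrays gave 4210 higher and 4741 lower (47% higher). With saline as the control, chosen after seeing the data, 4570 rows differed, and 4 of the 17 interferon-stimulated genes were higher and 1 lower (median change 0.217 above that of all genes, camera adjusted p = 0.387). Of 8 integrins 2 were higher and 1 lower than in saline (camera adjusted p = 0.662), of 15 matrix proteolysis genes 7 and 4 (camera adjusted p = 0.789), and of 18 matrix genes 7 and 1 (camera adjusted p = 0.137), so the shifts of these 3 lists did not hold either. The fall of metallothioneins and iron handling genes held, 3 of 11 lower (camera adjusted p = 0.000167; adjusted p = 0.158 with an estimated correlation). Cytokines and chemokines were lower than in saline, 7 of 15 lower and 1 higher (camera adjusted p = 0.000413; adjusted p = 0.125 with an estimated correlation). The calls of SF3A2, DNM2, STPG1, TMED4, CXCL3, TKT, TNFRSF10B, BBC3, RRM2, E2F1 and NF2 did not hold against saline (adjusted p from 0.0817 to 0.978).

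**Figure D3:**
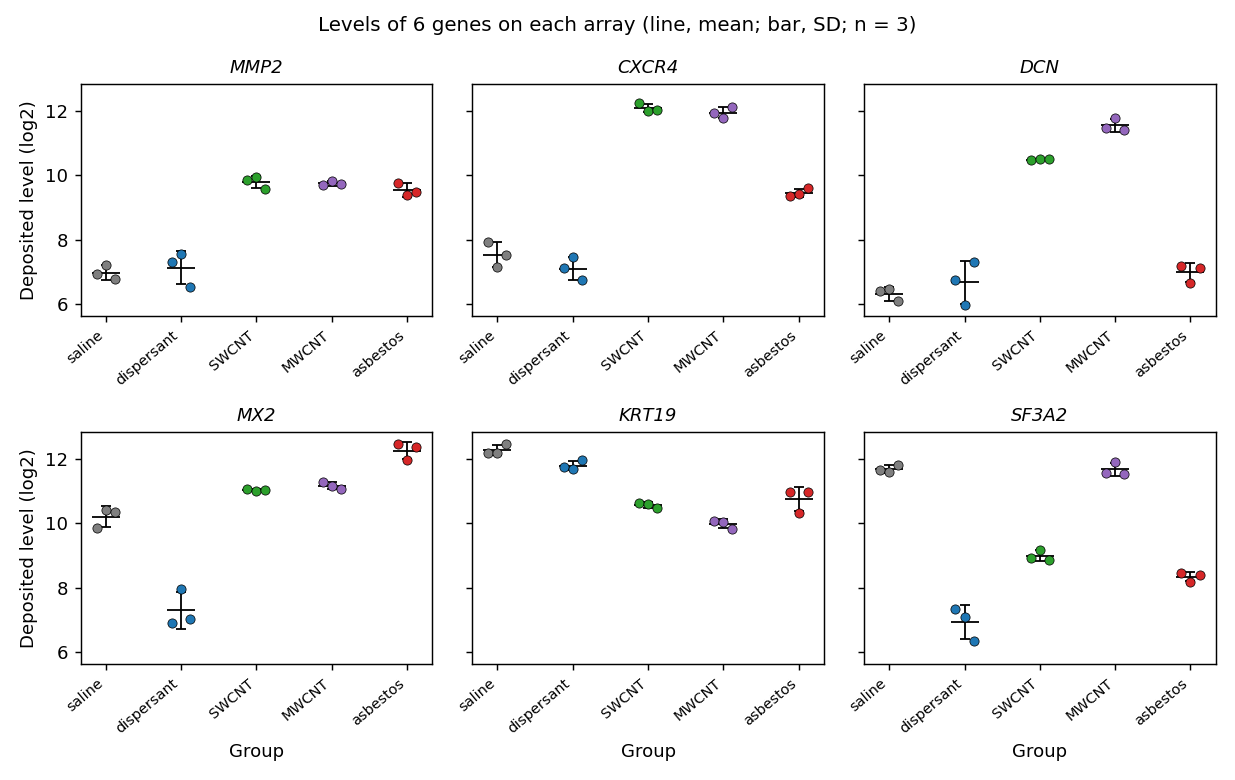
Deposited log2 level of 6 genes on each of the 15 arrays, with the group mean (line) and SD (bar), n = 3 per group. MMP2 lay between 6.545 and 7.554 on the control arrays and between 9.37 and 9.955 on the particle arrays, MX2 was lowest in dispersant (mean 7.298), and SF3A2 was high in saline and MWCNT (means 11.68 and 11.67).

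Asbestos was set against saline, its control in the study's design. KYNU, the kynurenine pathway enzyme kynureninase, was 29.2-fold higher (log2 change 4.87 ± 0.21 SE, adjusted p = 1.3e-08), with a mean log2 level of 11.45 ± 0.20 (SD, n = 3) against 6.586 ± 0.39. COL12A1 was 10.1-fold higher, the peptidase gene MME 9.57-fold and HACD2, an enzyme of very long fatty acids, 7.56-fold. CLTRN was 24.6-fold lower, and NFIC, a transcription factor (13.7-fold), FSCN1, the actin bundling protein fascin (11.5-fold), SF3A2 (10.1-fold) and KIAA1755 (9.71-fold) were also lower. The HACD2 change rested largely on asbestos replicate 2, without which its log2 change was 1.63 in place of 2.92.

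Interferon-stimulated genes were higher in asbestos than in saline as well, 15 of 17 with none lower (15 adjusted over the list alone), at a median 0.992 above all genes (camera adjusted p = 5.93e-06; adjusted p = 0.0466 with an estimated correlation). IFI44L was 4.82-fold and MX2 4.15-fold higher. Integrins fell, 4 of 8 with none higher (4 adjusted over the list alone; camera adjusted p = 0.00344; adjusted p = 0.0466 with an estimated correlation). Of these ITGA3 fell by 2.57 on the log2 scale. Immediate early genes, which respond first to growth signals, shifted down with 7 of 13 lower and 2 higher (7 and 2 adjusted over the list alone; camera adjusted p = 0.0278; adjusted p = 0.188 with an estimated correlation). Among them JUNB fell by 2.85. Cytokines and chemokines shifted down with 7 of 15 lower and 3 higher (7 and 3 adjusted over the list alone; camera adjusted p = 0.0268; adjusted p = 0.188 with an estimated correlation). CXCL1 was 5.08-fold and IL1A 4.01-fold lower. Metallothioneins and iron handling genes shifted down with 4 of 11 lower (4 adjusted over the list alone; camera adjusted p = 0.00344; adjusted p = 0.188 with an estimated correlation).

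MMP2 was 5.92-fold higher in asbestos than in saline (log2 change 2.57 ± 0.23, adjusted p = 5.36e-06), while MMP15, a membrane-bound metalloproteinase, was 3.54-fold lower. The matrix proteolysis list as a whole held 5 higher and 4 lower genes of 15 (5 and 4 adjusted over the list alone). Of 18 matrix genes 8 rose and 2 fell (10 and 2 adjusted over the list alone), with POSTN (periostin) 3.35-fold higher. Among 13 mesenchymal genes 4 rose and 4 fell (5 and 4 adjusted over the list alone). Their largest increases were FN1 (5.99-fold) and TWIST1 (3.38-fold). KRT19 was 2.87-fold lower and PDPN (podoplanin) 2.8-fold higher among 11 mesothelial and keratin markers, of which 1 rose and 2 fell (1 and 1 adjusted over the list alone). TKT was 2.17-fold lower and the cystine transporter gene SLC7A11 1.7-fold higher among 16 oxidative stress genes (2 higher and 2 lower, 1 and 1 adjusted over the list alone). PHLDA3 was 3.81-fold lower and GADD45A 2.31-fold higher among 13 p53 targets (3 higher and 3 lower, 3 and 3 adjusted over the list alone). CCNB1 and BUB1B, genes of mitosis, were 2.09-fold and 1.95-fold higher among 24 cell cycle genes (7 higher and 1 lower, 6 and 0 adjusted over the list alone). None of the 5 mesothelioma tumour suppressors passed the test. The SLC7A11 call ended without saline replicate 1 or 2 or asbestos replicate 1 or 2 (adjusted p up to 0.211, log2 change 0.42 without saline replicate 1). It also ended with centred arrays, a further quantile normalization, a fit of the compared arrays alone or the replicate number as a block (adjusted p from 0.0628 to 0.105). The BUB1B call ended without any array but asbestos replicate 3 (adjusted p up to 0.121) and in the centred data (adjusted p = 0.0546).

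In all, 8823 rows differed between asbestos and saline, 5311 higher and 3512 lower (60.2% higher), against 4590 and 4027 in centred data (53.3% higher), with the median row 0.179 higher. Of these, 4523 differed by 2-fold or more, 2178 higher and 2345 lower, so the balance turned among the larger changes. Asbestos replicate 2 stood apart from the other asbestos arrays on component 3 (score 54.1 against 14.8 and 20.0) and had the lowest array weight (0.409), and without it 8481 rows differed.

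**Figure D4:**
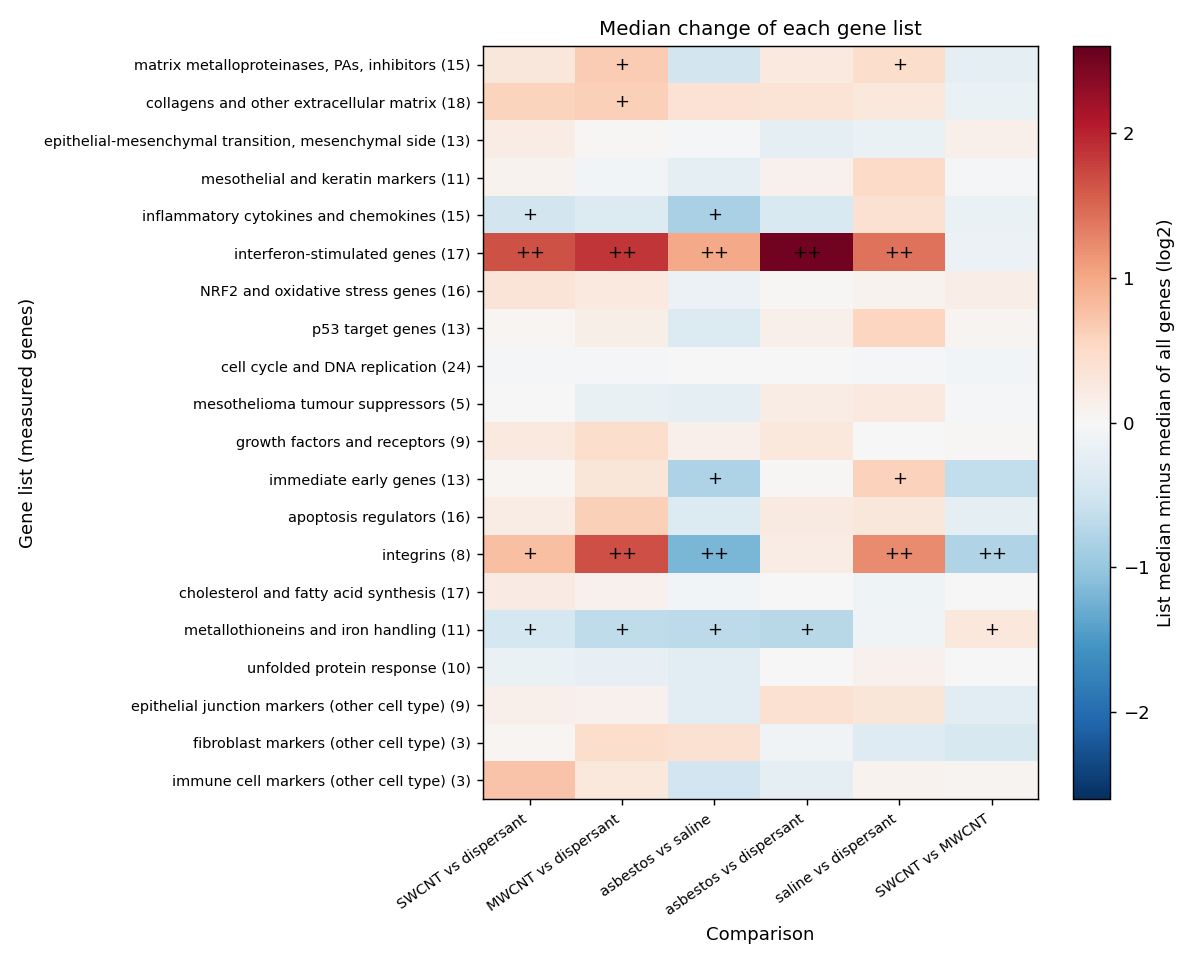
Median log2 change of each gene list minus the median of all genes (colour) in the 6 comparisons between groups, for the 20 lists with at least 3 measured genes. One plus sign marks a camera adjusted p under 0.05 with the preset correlation and a pair of plus signs marks one that also held with an estimated correlation, as for interferon-stimulated genes in all 5 comparisons against a control or between the controls.

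Against dispersant, the control that shared the surfactant, asbestos again had higher interferon-stimulated genes. MX2 was 31.1-fold (log2 change 4.96 ± 0.25 SE, adjusted p = 5.9e-08, n = 3 per group), IFI44L 16.5-fold and IFI6 15.9-fold higher. In all 16 of the 17 list members rose (17 adjusted over the list alone), at a median 2.51 above all genes (camera adjusted p = 1.49e-17; adjusted p = 0.000976 with an estimated correlation). CLTRN (12.9-fold), NAT1 (10.1-fold) and ATP5MK (8.91-fold) were the most reduced. MMP2 was 5.29-fold higher (log2 change 2.40 ± 0.23, adjusted p = 1.87e-05). Metallothioneins and iron handling genes fell in 5 of 11 cases (8 adjusted over the list alone; camera adjusted p = 2.16e-06; adjusted p = 0.0706 with an estimated correlation). Integrins, with 2 of 8 higher and 1 lower (2 and 1 adjusted over the list alone), did not shift as a list (camera adjusted p = 0.812). In all, 6048 rows differed, 4243 higher and 1805 lower (70.2% higher), against 2486 and 2669 in centred data (48.2% higher), and 3379 rows differed when only these 6 arrays entered the fit.

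The 2 passage controls were compared to see what the dispersant itself changed, and they differed widely. SF3A2 was 26.8-fold higher in saline than in dispersant (log2 change 4.75 ± 0.23 SE, adjusted p = 2.63e-08, n = 3 per group), FSCN1 17.8-fold and RELA, a subunit of the inflammatory regulator NF-kB, 17.3-fold. KYNU (6.38-fold), NAA16 (4.65-fold) and TMED4 (4.6-fold) were lower in saline, and MMP2 gave a log2 difference of -0.16 ± 0.23 (adjusted p = 0.664). In saline 14 of 17 interferon-stimulated genes were higher (14 adjusted over the list alone; camera adjusted p = 5.74e-11; adjusted p = 0.00662 with an estimated correlation), as were 5 of 8 integrins (5 adjusted over the list alone; camera adjusted p = 0.00018; adjusted p = 0.0124 with an estimated correlation). The matrix proteolysis list (6 of 15 higher and 1 lower, 6 and 1 adjusted over the list alone; camera adjusted p = 0.0158; adjusted p = 0.11 with an estimated correlation) and immediate early genes (6 of 13 higher, 7 adjusted over the list alone; camera adjusted p = 0.0288; adjusted p = 0.21 with an estimated correlation) also shifted up. In all, 5293 rows differed, 3280 higher and 2013 lower in saline (62% higher), against 2898 and 3197 in centred data (47.5% higher), and 3268 rows differed when only these 6 arrays entered the fit.

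The nanotube types differed from each other less than from dispersant. FKBP10, a chaperone of collagen folding, was 8.28-fold lower in SWCNT than in MWCNT (log2 change -3.05 ± 0.13 SE, adjusted p = 3.66e-08, n = 3 per group), DNM2 7.83-fold and the kinase gene HIPK2 7.61-fold. R3HDM2 (3.24-fold), SUMF2 (2.91-fold) and RBFOX2, a splicing regulator (2.79-fold), were higher in SWCNT. Integrins were lower, 4 of 8 (4 adjusted over the list alone; camera adjusted p = 0.00204; adjusted p = 0.0477 with an estimated correlation), and metallothioneins and iron handling genes shifted up with 2 of 11 higher (4 adjusted over the list alone; camera adjusted p = 0.0291; adjusted p = 0.479 with an estimated correlation). MMP2 differed by 0.05 ± 0.23 on the log2 scale (adjusted p = 0.923), and 1 of 17 interferon-stimulated genes, IFI6, differed (1 adjusted over the list alone). In all, 2172 rows differed, 597 higher and 1575 lower in SWCNT (27.5% higher), against 37.9% higher after a further quantile normalization (1041 and 1704). Leaving out any 1 of the 6 arrays (SWCNT replicate 1, 2 or 3, MWCNT replicate 1, 2 or 3) lowered the count to between 1276 and 1388, and array weights raised it to 4225.

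Whether nanotubes and asbestos changed the same genes was asked by setting each particle's change, against its own control, beside the others. Of the 17 interferon-stimulated genes, 14 rose in SWCNT and MWCNT against dispersant and in asbestos against saline. In 7 of the 17 the change was larger in SWCNT than in asbestos, and in 7 it was larger in MWCNT than in asbestos (8 and 7 adjusted over the list alone), but these changes start from unlike controls. With dispersant as the control of asbestos too, chosen after seeing the data, none was larger in the nanotubes, and 8 of 17 were smaller in SWCNT (14 adjusted over the list alone) and 11 in MWCNT (11 adjusted over the list alone). The list then lay lower in SWCNT (camera adjusted p = 5.76e-15; adjusted p = 0.00191 with an estimated correlation) and MWCNT (camera adjusted p = 2.74e-07; adjusted p = 0.0148 with an estimated correlation) than in asbestos. MMP2, PLAU, SERPINE2 and TIMP4 of the matrix proteolysis list and COL12A1, COL4A1, COL6A1, COL6A2, POSTN and THBS2 of the matrix list rose in all 3 comparisons, and KRT19, CSF2, CSF3, IL1B and MT1F fell in all 3. For MMP2 the SWCNT effect differed from the asbestos effect by 0.09 ± 0.33 on the log2 scale (adjusted p = 0.882) and the MWCNT effect by 0.04 ± 0.33 (adjusted p = 0.937). FSCN1 and SF3A2 rose in the nanotube comparisons, against dispersant, and fell in the asbestos one, against saline, with differences of effect of 5.47 ± 0.31 and 5.39 ± 0.32 for SWCNT (adjusted p = 3.85e-07 and 4.89e-07) and 7.60 ± 0.31 and 8.07 ± 0.32 for MWCNT. NFIC for SWCNT (5.03) and DNM2 for MWCNT (7.50) followed, and the largest differences the other way were KYNU (-3.09 for SWCNT, -3.74 for MWCNT), MME (-3.46 and -4.21), LYPLAL1 for SWCNT (-3.16) and TMED4 for MWCNT (-3.24). With dispersant as the control of asbestos too, these differences shrank, and neither FSCN1 nor SF3A2 was lower in asbestos than in the control. They came to 1.32 for FSCN1, 0.64 for SF3A2, 1.28 for NFIC, -1.64 for MME, -1.28 for LYPLAL1 and -0.42 for KYNU in SWCNT. In MWCNT they were 3.45 for FSCN1, 3.32 for SF3A2, 3.70 for DNM2, -2.39 for MME, -1.06 for KYNU and -1.04 for TMED4. The calls of SF3A2 and KYNU for SWCNT (adjusted p = 0.152 and 0.323) and TMED4 for MWCNT (adjusted p = 0.178) ended, and the others held.

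Over all rows, the effect of SWCNT differed from that of asbestos in 4037, 2771 of them with the larger value in SWCNT (68.6%, against 2378 of 4733 or 50.2% in centred data), and the effect of MWCNT differed in 7577, 4125 with the larger value in MWCNT (54.4%, against 3702 of 8415 or 44% after a further quantile normalization). The SWCNT and MWCNT changes correlated across rows with r = 0.8, where unchanged groups simulated against the same dispersant arrays gave 0.501, and their covariance was 0.482 against a simulated 0.0415. They shared 3339 higher rows (1153 for independent lists) and 1034 lower rows (154), and 15 rows went opposite ways. With the 3 dispersant arrays split 1 against 2 between the effects in all 6 ways, chosen after seeing the data, r was 0.592 to 0.623 and the covariance 0.412 to 0.421. All 3 arrays come from 1 treatment, so a change of the dispersant cells themselves stays in both effects under every split. SWCNT and asbestos changes, which share no control, correlated with r = 0.346, with 1494 rows higher in both (1066 for independent lists), 786 lower in both (201) and 748 opposite. MWCNT and asbestos changes had r = 0.0253 (0.0082 to 0.0492 when each replicate was left out). For this pair 1200 rows were higher in both (1415 for independent lists), 928 lower in both (439) and 1978 opposite. With dispersant as the control of asbestos r was 0.807 for SWCNT and 0.695 for MWCNT (simulated 0.5 for each), and the covariances exceeded the simulated ones by 0.353 and 0.414. Saline against dispersant, which held no particles, gave nearly the same for MWCNT (r = 0.69, excess covariance 0.395), and r = 0.418 for SWCNT and 0.296 for asbestos (excess covariances 0.156 and 0.111, simulated r 0.501 for each). The value for MWCNT and asbestos therefore does not measure a particle effect alone.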

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

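In this part the counts over other splits of the arrays, and the choice of dispersant as the control of both particle kinds, were made only after the main results were seen.

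The differences between particle effects were singled out because a test of the difference itself called them: 4037 rows responded differently to SWCNT than to asbestos, and 7577 rows to MWCNT. Each effect was taken against its own control, and the controls themselves differed in 5293 rows. With dispersant as the control of both, 628 rows differed for SWCNT, so a difference between the control groups may account for most of that count, and 446 of the 628 had also differed in that direction against their own controls. For MWCNT 4406 rows still differed, 3919 of them called in that direction before, which lies between the bounds set for and against the controls as the cause and leaves their share open. A difference in how MWCNT and asbestos fibres act on the cells, which the design names, stays untested against a drift of separately passaged cultures, since each treatment is 1 set of wells.

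Of 100 drawn splits of the 12 arrays, the real one alone gave as many rows for SWCNT against asbestos (4037, highest other 3025). The same held for MWCNT against asbestos (7577, highest other 4591). A split that mixes groups which differ has a wider spread and finds fewer rows (the median of the other splits was 0). The real split was therefore favoured in advance, and these counts cannot exclude a chance assignment of the arrays. They also cover only the spread between arrays and not that between cultures. Two-group comparisons of 3 arrays against 3 have 10 splits, too few for a share under 0.05. There the real split was the 1 of 10 with as many changed rows for SWCNT against dispersant (5564, highest other 0), MWCNT against dispersant (8441, other 1), asbestos against saline (8823, other 0), asbestos against dispersant (6048, other 1), saline against dispersant (5293, other 0) and SWCNT against MWCNT (2172, other 0). For the number of shifted lists, 2 of 10 splits gave as many as SWCNT against dispersant (4, highest other 4) and 4 of 10 as many as asbestos against dispersant (2, other 2). The real split was the 1 of 10 with as many shifted lists for MWCNT against dispersant (5, other 2), asbestos against saline (5, other 2), saline against dispersant (4, other 3) and SWCNT against MWCNT (2, other 0).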

How the results depend on the processing

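The values with saline as the control of the nanotubes or dispersant as that of asbestos were chosen after seeing the data; the others were planned. Of 118 values for named genes, 111 kept their direction and side of the threshold under all 8 settings planned for them, and 108 also without each replicate; SLC7A11, BUB1B, MSLN, E2F1, NF2 and CXCL3 are named in the report. Quantile normalization, centring and the 1.5-fold minimum moved no count of changed rows by over 1.5 times, but the rows called were not all the same. Centring shared 3585 of the 5564 rows for SWCNT against dispersant and 6905 of the 8441 for MWCNT against dispersant. For asbestos against saline it shared 8102 of the 8823. Fitting only the arrays compared gave 3379 rows for asbestos against dispersant and 3268 for saline against dispersant (fewer arrays set the spread). Leaving out the lowest rows gave 3 shifted lists for asbestos against saline and turned the correlation of MWCNT and asbestos effects from 0.0253 to -0.040, trended robust variances gave 4 lists for asbestos against dispersant, and array weights gave 4225 rows for SWCNT against MWCNT; the cause was not tested. Averaging the rows of a gene leaves fewer rows to test, and gave 2450 (SWCNT against dispersant), 3394 (MWCNT against dispersant), 3682 (asbestos against saline), 2620 (asbestos against dispersant), 2110 (saline against dispersant), 845 (SWCNT against MWCNT), 1589 and 3032 (the differences of SWCNT and MWCNT effects from asbestos). An estimated inter-gene correlation left, in that order of the first 6, 1, 2, 2, 1, 2 and 1 shifted lists. Without each replicate, SWCNT against MWCNT gave 1276 to 1388 rows and 1 to 2 lists.

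With saline as the control, 7201 rows differed for SWCNT and 4570 for MWCNT, and 2 lists shifted for each. Of the rows higher against dispersant, 42.4% in SWCNT and 33.4% in MWCNT were also higher against saline, and 61.4% and 37.6% of the lower rows were also lower. Of the higher rows 402 in SWCNT and 51 in MWCNT were lower against saline, and of the lower rows 5 and 24 were higher. With dispersant as the control of asbestos, the effects correlated with r = 0.807 (SWCNT) and 0.695 (MWCNT), and 628 and 4406 rows differed. Against saline some named genes changed sign, but none of these passed the test (adjusted p from 0.398 to 0.978), so no reversal was shown. They were BBC3 (0.087), RRM2 (-0.11), E2F1 (-0.30), LATS2 (-0.030) and NF2 (-0.21) in SWCNT, and SF3A2 (-0.011) and NF2 (-0.016) in MWCNT. The cause was not tested. The uncalled MMP2 differences also changed sign: the SWCNT effect minus the asbestos effect was -0.045 after quantile normalization, -0.062 after centring and -0.20 to 0.30 without each replicate, and the MWCNT effect minus the asbestos effect -0.13, -0.11, -0.019 with array weights and -0.25 to 0.25 without each replicate. Without each replicate MMP2 ran from -0.46 to 0.048 for saline against dispersant and from -0.034 to 0.15 for SWCNT against MWCNT.

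The replicate numbers did not pair the arrays: none of 30 same-number pairs had deviations correlated above 0.1 (-0.0586 to 0.038), and 7 of 15 arrays matched best with their own number. With the replicate block the counts were 5248, 8191, 8506, 5751, 4922, 1836, 3695 and 7295 in the order above, all within 1.5 times, and of the named genes the SLC7A11 call ended (adjusted p = 0.0628). An offset before the log was not run, since the values were already log2. Rows that may have been dropped for low signal limit what can be seen of genes near background.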

Other observations

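All tests and gene lists in this part were chosen after the results were seen.

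Ribosomal protein and respiratory chain genes shifted as lists in several comparisons with the preset correlation, and in none with an estimated one. Of 82 cytosolic ribosomal protein genes 37 were lower and 2 higher in saline than in dispersant (median relative to all genes -0.466, camera adjusted p = 1e-12; adjusted p = 0.0986 with an estimated correlation), and 31 were lower and 4 higher in MWCNT than in dispersant (camera adjusted p = 1.37e-10; adjusted p = 0.159 with an estimated correlation). In asbestos against saline 56 were higher and none lower (camera adjusted p = 5.42e-08; adjusted p = 0.238 with an estimated correlation). Of 73 respiratory chain and ATP synthase genes 34 were lower and none higher in saline than in dispersant (camera adjusted p = 1.01e-12; adjusted p = 0.0789 with an estimated correlation), led by COX5A (log2 change -1.28). In asbestos against saline 39 were higher and 2 lower (camera adjusted p = 1.71e-05; adjusted p = 0.238 with an estimated correlation), and the 2 that fell were ATP5MK and ATP5IF1. Ribosomal protein genes also shifted down relative to all genes in SWCNT against dispersant (median -0.219, camera adjusted p = 0.0405, or 0.646 with an estimated correlation). There 5 of the 82 were higher and 2 lower, and their own median log2 change was 0.0476. The list shifted up in SWCNT against MWCNT, with 10 higher and 1 lower (camera adjusted p = 3.09e-12, or 0.107 with an estimated correlation). It did not pass in asbestos against dispersant (camera adjusted p = 0.391). Respiratory chain genes shifted down in MWCNT against dispersant, with 20 of 73 lower and 3 higher (camera adjusted p = 6.99e-07, or 0.159 with an estimated correlation). Relative to all genes they also shifted down in asbestos against dispersant (median -0.239, camera adjusted p = 0.0284, or 0.493 with an estimated correlation). There 6 were higher and 4 lower, and their own median log2 change was 0.0455. They shifted up in SWCNT against MWCNT, with 5 higher and none lower (camera adjusted p = 4.63e-10, or 0.107 with an estimated correlation). They did not pass in SWCNT against dispersant (camera adjusted p = 0.248).

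Genes of antigen processing and presentation, which interferon also induces in many cells, rose in 7 of 15 cases in SWCNT against dispersant with none lower (camera adjusted p = 0.0405; adjusted p = 0.392 with an estimated correlation) and in 9 of 15 in asbestos against dispersant (camera adjusted p = 0.0284; adjusted p = 0.355 with an estimated correlation). The list did not pass in MWCNT against dispersant (camera adjusted p = 0.0841, with 6 of 15 higher), saline against dispersant (0.0776), asbestos against saline (0.699) or SWCNT against MWCNT (0.945). TAP2, a subunit of the peptide transporter, changed more than the other members in both comparisons that follow: it was 3.34 higher in MWCNT and 3.54 higher in saline than in dispersant on the log2 scale, and changed by -2.17 in asbestos against saline. Cilium assembly genes did not shift as a list in any of the 6 comparisons (lowest camera adjusted p = 0.0638), while TCTN2 fell by 3.35 in SWCNT and by 3.42 in MWCNT against dispersant and IFT57 fell by 1.66 and 1.45.

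A set of genes was high in saline and MWCNT and low in dispersant, with SF3A2, FSCN1 and RELA at its head. Chosen without dispersant replicate 3 and measured against it, 778 genes were at a median 1.34 log2 above dispersant in saline. All 3 particle stocks held the dispersant, so exposure to it alone would leave the particle groups near dispersant. By the bounds set for this, asbestos, at 0.543 (0.372 to 0.451 times that of saline by bootstrap), stayed near dispersant. SWCNT, at 0.738 (0.512 to 0.599 times), lay between the bounds, and MWCNT, at 1.55 (1.11 to 1.22 times), lay above them. These ranges rest on 1 dispersant array and cannot cover the spread between dispersant arrays or cultures. The saline arrays both chose the genes and gave the 1.34, which may lie too high for that reason. The ratios to saline may then lie too low, so the place of asbestos is not secure. The medians are also not relative to all genes, so the place of SWCNT is not secure either. The all-gene median against dispersant was 0.267 in SWCNT, 0.285 in asbestos, 0.202 in MWCNT and -0.0162 in saline. The MWCNT level was known before the test was written and restates the pattern, so the explanation stays open. A trend with local gene density was looked at in 697 genes chosen without saline and dispersant replicates 3. Their median difference between those 2 arrays was 1.41, and 1.33 after the medians of 20 density bins were taken off. The ratio was 0.913 to 0.954 by bootstrap, with 1 array per group. The set had a median of 20 neighbours against 14 for all genes. The bin medians ran only from -0.103 to 0.206, so a set chosen for being higher in saline had to keep most of its difference. The values show that the bin medians are small beside 1.41, and they decide no more about density. Across genes, Spearman's rho with gene density was 0.163 for the saline against dispersant change and -0.222 for the asbestos against saline change. A difference between hybridization slides and a state that each culture settled into over 16 passages may each remain candidate explanations, and neither was tested.

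Relative to all genes, the 105 measured genes of chromosome 18 were lower in both nanotube groups than in dispersant, with a median log2 change of -0.33 in MWCNT and -0.313 in SWCNT (adjusted p = 0.00788 and 0.00552 over 138 chromosome comparisons, of which 10 passed; among those that passed, the largest median on another chromosome was 0.23, and among those that did not, chromosome 13 reached 0.298 in asbestos against saline). In SWCNT 9 of the 105 genes fell and 5 rose by the test of single genes, in MWCNT 22 fell and 6 rose, and in asbestos against saline 45 rose and 7 fell, where the chromosome's median of 0.288 relative to all genes did not pass (adjusted p = 0.364) and the sets matched on density and level already reached 0.179; in saline against dispersant 18 fell and 5 rose, with a median of -0.172 that did not pass either (adjusted p = 0.5, matched sets -0.0927). Relative to each gene's mean, the chromosome stood between 0.168 and 0.212 on the dispersant arrays and 0.249 and 0.285 on the asbestos arrays, against -0.0775 to 0.00925 in saline, -0.152 to -0.121 in SWCNT and -0.231 to -0.199 in MWCNT. A trend with gene density and level is argued against for the nanotube comparisons only, since 0.01% of the matched sets lay as low in MWCNT. The matched sets draw genes singly from fixed changes. The chromosome p-values therefore count neither the spread between arrays nor genes that move together. In that comparison 72.4% of the chromosome's genes lay below the median of all genes. The chromosome was singled out by its low median, which a few strong genes do not set. This share therefore restates the low median and is no separate test. A chromosome copy number that differs between the nanotube and dispersant cultures, in whichever of them it changed, is a candidate explanation and a hypothesis only. DNA was not measured in the data used here. The shift ran through all 3 parts of the chromosome with equal numbers of measured genes (the smallest was -0.281 in MWCNT and -0.26 in SWCNT). A chromosome chosen for its low median tends to be low in each part, so these values are no separate support. The parts also shared a direction in saline against dispersant (-0.215 to -0.0838) and asbestos against saline (0.163 to 0.442), where the chromosome did not pass. They did not in the other 2 comparisons. Chromosomes 3, 6, 7, 10 and 14 also had comparisons that passed.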
